A study of Mus musculus with 2 samples.

How the data were processed

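RNA from mouse urogenital ridges at embryonic day 14.5 was measured on 2 single-colour Affymetrix oligonucleotide arrays. The ridge is the embryonic tissue that carries the Müllerian and Wolffian ducts, and the gonads had been removed. Per the labels, ridges were sorted by genotype with a YFP reporter, about 100 ridges went into each pool, the strain was a mix of C57Bl/6 and 129SVEV, and total RNA was extracted with Trizol and labelled with biotin. Group membership was taken from the genotype in the labels. The heterozygous pool (Misr2+/-) and the homozygous pool (Misr2-/-) each had 1 array.

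The deposited value table holds 1 linear intensity per probe set and array, and GCOS and MAS5 are named without a version or a role in it per the submitters' processing notes. A second table, the authors' deposited table of fold changes, lists 739 probe sets with an intensity for each pool and a signed fold, treated here as a score, which is positive where the homozygous pool was higher. Its intensities equalled those of the deposited value table multiplied by 0.9007 for the homozygous and by 1.0898 for the heterozygous array, so that its scale differs from the value table by a ratio of 1.21. The recomputed fold differed from the authors' fold by at most 0.0005. The filter behind the 739 probe sets and the scaling of the deposited intensity values are not given in the sources used here. No detection calls were used.

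The value table held 45101 probe sets, of which 64 were controls and were left out of all gene values. Of the other 45037, 34945 had 1 gene symbol in the platform annotation, 932 had several and 9160 were not listed there with a gene. No gene was named from a probe set with several symbols. The Entrez identifier matched the mouse RefSeq gene table of assembly GRCm38.p6 for 34741 probe sets, and 0 symbols needed an update. That table was used for names and chromosomes only, and no coordinates are printed because the array's genome build is not given in the sources used here. Of the 564 genes in the lists below, 50 had no probe set named for them and were not analysed here.

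Signals were used as deposited. The floor was each array's median over probe sets that are not controls, 116.5 in the heterozygous and 139.4 in the homozygous pool. A probe set counted as measured when at least 1 signal reached its array's floor, and signals under the floor were set to it, so that a fold against such a value is a lower bound and is written as at least that size. Each gene was represented by the probe set with the highest mean signal among those named for that gene alone. The log2 difference is homozygous minus heterozygous. The array medians differed by 0.26 on the log2 scale, and differences are given relative to that shift unless they are said to be as deposited. This reference was chosen after the arrays' medians were seen, and it equals dividing each array by its median.

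The arrays' number limits the precision. The spread between probe sets of the same gene was taken as a measure of technical noise, as the SD of the difference between the log2 differences of a gene's 2 brightest measured probe sets divided by the square root of 2. It leaves out variation between pools and any technical variation that a gene's probe sets share. It can include real differences between the sequences that they detect. For a gene list, the median log2 difference of its measured members was set against 10000 random lists of the same size matched on mean signal in 20 bins. Lists under the 2.5th or above the 97.5th percentile are reported as outside the central 95% of random lists, as a description of these 2 arrays. Lists with under 3 measured members were not compared. With 1 array per group no p-values, standard errors or tests between genotypes are given.

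The 35 gene lists, the floor, the 2-fold threshold and the rule for named genes were fixed before the data were examined. Named were Amhr2, Wif1, Sp7, Axin2, Lef1, Mmp2, Wnt7a and the sex-linked genes in any case. Added to them were the 12 genes with the highest and the 12 with the lowest difference whose other measured probe sets differed in the same direction (unnamed transcripts left out), and up to 4 members of each list with the largest absolute difference. Other genes were named after their values had been seen, as stated where they appear. The genes fixed by name include some known from published work on the receptor. Alternatives fixed beforehand were scaling to the 75th percentile, quantile normalization, a loess fit on mean signal, floors at the 40th, 60th and 75th percentile, no floor with a pseudocount of 16, the median of a gene's probe sets, leaving out probe sets whose identifiers mark shared or cross-hybridising sequences, and thresholds of 1.5-fold and 3-fold. Scaling to the median, to the constants behind the authors' table and to the hybridisation spikes was added after the data were seen. An alternative based on detection calls was not run.

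The procedure was tested on simulated data for 11354 genes. Differences were simulated in genes with a heterozygous signal of at least 4 floors, so that the recovery of dimmer genes was not tested. The procedure recovered 100 of 100 genes simulated with a 3-fold difference and 92 of 100 simulated with a 2.5-fold difference, and it called 0 of 11154 unchanged genes. Of 100 simulated lists of 15 unchanged genes, 4 lay outside the central 95% of random lists, and 99 of 100 lists shifted by 0.3 on the log2 scale lay above the 97.5th percentile. The simulated noise was independent for each probe set, with 1 SD at all signals (0.23, that between probe sets of the same gene). It held no variation between pools and no genes that vary together. The simulation therefore checks the computation and gives no rate of false calls for these 2 pools. Computations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.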

Results

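Transcript levels were measured in agonadal urogenital ridges of mouse embryos at E14.5, in 1 pool of about 100 ridges heterozygous and 1 pool of about 100 ridges homozygous for a deletion of Misr2. Misr2, named Amhr2 in the annotation, encodes the type II receptor for Müllerian inhibiting substance (MIS, also called anti-Müllerian hormone or AMH), the testis hormone that makes the Müllerian duct regress in males. The labels describe the heterozygous ridges as responsive to MIS and the homozygous ridges as unresponsive, so that the comparison addresses which transcripts of the ridge depend on the receptor. There were no replicates, and differences between the pools were not tested.

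Of 45037 probe sets, 23379 were measured in at least 1 pool, and they represented 11432 genes. Signals ran from 0.1 to 17015.2 in the heterozygous and from 0.1 to 18718.8 in the homozygous pool. Over measured probe sets the log2 signals of the 2 arrays had a Pearson r of 0.979, a correlation across probe sets, which are not independent replicates. The homozygous array was brighter, with a median of 139.4 against 116.5, and relative to this shift of 0.26 on the log2 scale 95.6% of measured probe sets lay within 1.5-fold. The spread between probe sets of the same gene had an SD of 0.23 on the log2 scale over 5264 genes, from 0.27 at signals of 129 to 360 to 0.19 at signals above 1818. It covers only what differs between a gene's probe sets on these 2 arrays.

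The 2 pools differed at least 2-fold in 50 genes relative to the median shift, with 26 higher and 24 lower in the homozygous pool. As deposited, the same threshold gave 86 higher and 10 lower genes, so that 89.6% instead of 52.0% of the genes past it were higher in the homozygous pool. Scaled to the hybridisation spikes the split was 4 higher and 96 lower. At 3-fold, relative to the median shift, 9 genes were lower and 1, Spry4, was higher in the homozygous pool. Of the 24 lower genes, 12 had a homozygous signal under the floor, and of the 26 higher genes, 3 (Nudt12, Tfap2c and an unnamed transcript, looked up after their values were seen) had a heterozygous signal under it. Among the 50 genes, 15 had further measured probe sets, and in 12 of these all probe sets differed in the same direction; the exceptions, looked up afterwards, were Abcb8, Mpzl2 and Rbm12b2. As deposited, a value less than 0.26 below 0 turns positive, and against the spikes a value less than 0.40 above 0 turns negative.

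Amhr2, the targeted gene, had the lowest value of all measured genes. Its brightest probe set gave a signal of 1549.6 in the heterozygous and 10.2 in the homozygous pool, at least 13.3-fold lower in the latter. Its other probe sets went from 1047.8 to 27.7 and from 181 to 2.8, so that all 3 lay under the floor in the homozygous pool, in the direction of the genotype labels. Without probe sets marked as shared or cross-hybridising, only the dim one was left and the log2 difference as deposited was -0.38, a bound set by the floor. Amhr2 lies on chromosome 15. Where its probe sets lie relative to the deleted part is not given in the sources used here. Whether the drop reflects the deleted sequence itself or a lower level of the rest of the transcript is therefore not known.

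Several developmental regulators were next to Amhr2 among the lowest genes. Msx2, a homeobox gene activated by BMP signalling, had signals of 556.6 and 100.7 in the heterozygous and homozygous pool, at least 4.78-fold lower in the latter. Wif1, a secreted inhibitor of WNT ligands, had signals of 397.8 and 65.4, at least 3.41-fold lower. Dlx5, another homeobox gene, was at least 3.51-fold lower, and Gata5, a zinc finger transcription factor, at least 3.24-fold lower. The zinc finger transcription factors Sp6 and Sp7 (osterix, a regulator of bone formation) were at least 2.66-fold and at least 2.35-fold lower. Sp7 also lies on chromosome 15, near Amhr2.

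Other genes among the 12 lowest had different functions. Ednrb, the endothelin receptor type B, went from 1926.7 to 641.7, 3.59-fold lower, and it was the one gene of these 12 with both signals above the floor. Its 3 measured probe sets had log2 differences of -1.85, -1.69 and -1.25. Galnt5, an enzyme of mucin-type glycosylation, was at least 4.11-fold lower, Zap70, a tyrosine kinase of T cell receptor signalling, at least 3.97-fold, and Syt1, a calcium sensor of synaptic vesicles, at least 3.15-fold. Zap70, Syt1, Msx2 and Sp6 had further probe sets under the floor in both pools. Each of these folds rests on 1 probe set. Rpl39l, which encodes a ribosomal protein paralogue, was at least 2.37-fold lower. The germ cell markers Dazl, Dppa3 and Dppa5a were also lower in the same pool, by factors of 2.28, 2.18 and 2.09.

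The genes with the highest values in the homozygous pool included regulators of signalling. Spry4, an inhibitor of FGF and ERK signalling, had signals of 169.4 and 637.9 in the heterozygous and homozygous pool, 3.15-fold higher in the latter, although its other measured probe set differed by only 0.30 on the log2 scale. Sall1, a zinc finger transcription factor needed for kidney development, went from 342.2 to 1027.4 and was 2.51-fold higher. Npy, the neuropeptide Y gene, went from 426.7 to 1194.5 and was 2.34-fold higher. Il17d, which encodes a cytokine, was 2.57-fold higher.

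The remaining genes among the 12 highest were mostly dim in the heterozygous pool. Rccd1 was 2.83-fold higher in the homozygous pool, Fbxo10, which encodes an F-box protein, 2.77-fold, Clic6, of the chloride intracellular channel family, 2.69-fold, and Slc45a1, a sugar transporter, 2.56-fold. Car14, a membrane-bound carbonic anhydrase, was 2.55-fold higher, with a heterozygous signal of 124.1 against a floor of 116.5. Aspn (asporin, a small leucine-rich matrix proteoglycan) was 2.38-fold higher, but its other probe set differed by 0.11 on the log2 scale. Tnfaip6, which encodes a hyaluronan-binding protein, was 2.33-fold and Tmem59l 2.21-fold higher. Among the 12 highest, the spread between probe sets of the same gene at their signals was 0.24 to 0.27 on the log2 scale.

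**Figure D1:**
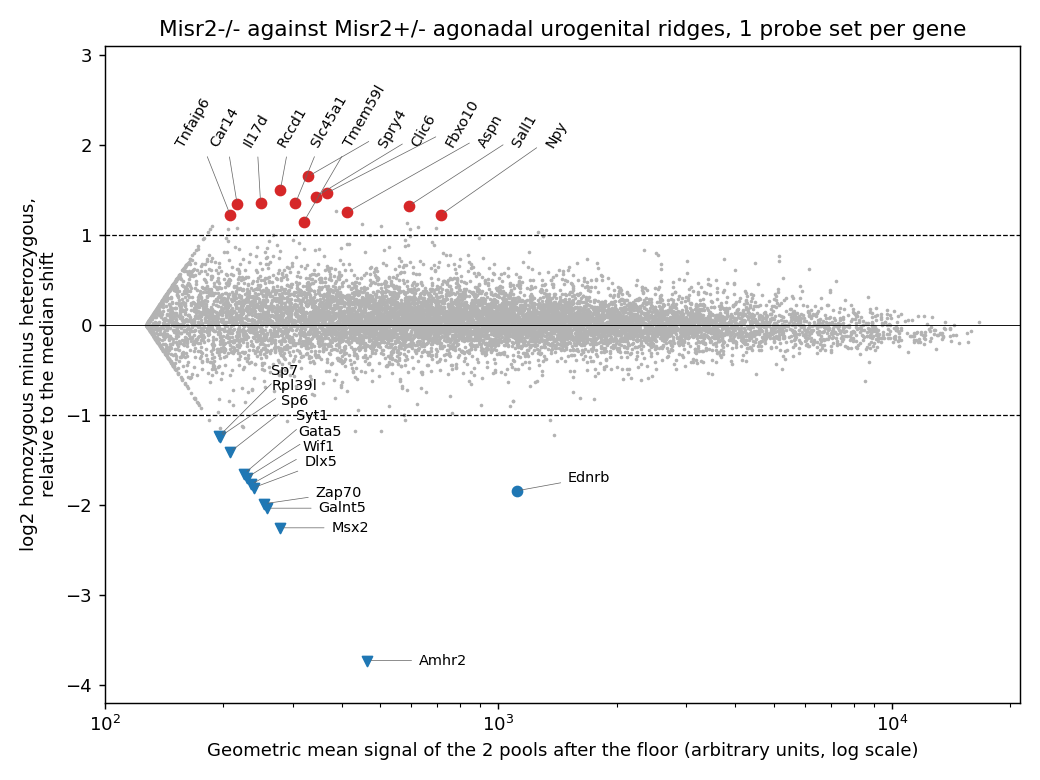
Each dot is 1 of 11432 genes, with the geometric mean signal of the 2 pools after the floor (arbitrary units, log scale) on the x axis and the log2 difference, homozygous minus heterozygous, relative to the median shift on the y axis; dashed lines mark 2-fold, blue triangles are lower bounds with a homozygous signal under the floor, and blue and red circles have both signals measured. Amhr2 lies at -3.73, the other labelled genes between -2.26 and 1.65, and most of the 12 labelled lower genes lie on the edge that the floor sets.

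Genes that respond to the Smad pathway shared by BMPs and AMH were lower in the homozygous pool as a group. Of 15 measured members 12 were below and 3 above 0, and the median log2 difference was -0.38, lower than all 10000 matched random lists, whose central 95% ran from -0.09 to 0.14. Msx2, Dlx5, Sp7 and Smad6, an inhibitory Smad induced by BMPs, were at least 2-fold lower. Smad6 was measured well above the floor in both pools, at 1933.3 and 987.7, 2.34-fold lower. Chosen after their values were seen, Id4 (-0.84), Msx1 (-0.82) and Bambi (-0.60) were also lower, while Id1 (-0.00), Id3 (-0.05) and Id2 (0.22, with probe sets in both directions), which are among the best known BMP targets, were close to 0 or above. Without Sp7, listed from prior knowledge of work on this receptor, the median was -0.34, also lower than all random lists. The list's median stayed below 0 as deposited, at -0.12, and against the spikes, at -0.79. Germ cell and fetal testis markers, listed with the cell types, were lower in the same pool, with medians of -0.72 and -0.47.

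Components of the receptor pathway itself did not share this difference. Of 10 measured receptors and Smads, 5 were above and 5 below 0, and the median of 0.03 stood at percentile 64.0 of random lists, although the mean was -0.31 because of Amhr2. The median without Amhr2 was 0.10, at percentile 92.4. Smad1 and Smad5, which transmit the signal, had log2 differences of 0.26 and 0.23, although probe sets of each differed in both directions, and Bmpr1b, a type I receptor, of 0.21. All 3 values turn negative against the spikes.

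Genes reported as regulated in Müllerian duct regression went in both directions. The median of the 14 measured members was -0.12 (0.13 as deposited, where it turns positive), at percentile 0.6 of random lists, and without Amhr2 it was -0.10, at percentile 2.26. Amhr2, Wif1 and Sp7 were at least 2-fold lower. These 3 were listed from prior knowledge of work on this receptor that can include these arrays, so they are not independent evidence of the direction, and without them the median of 11 members was -0.08, at percentile 5.04, inside the central 95%. Wnt7a, a ligand of the Müllerian duct epithelium, was 1.57-fold higher, from 444 to 832.9, and Wnt4, a ligand needed for the duct to form, was 1.41-fold lower. Mmp2, a matrix metalloproteinase, and Lef1, a nuclear partner of beta-catenin, had log2 differences of -0.15 and -0.18, less than their probe set spread, and both turn positive as deposited.

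Targets of canonical WNT signalling were mostly higher in the homozygous pool. Of 16 measured targets 11 were above and 5 below 0, with a median of 0.16 (-0.25 against the spikes) at percentile 97.1 of random lists, inside the central 95%. The list passed the upper end of that range under quantile normalization (97.9), with the floor at the 60th percentile (99.5) and with the median of probe sets (99.9), and stood at 78.9 with the floor at the 75th percentile and at 80.3 without a floor. Nkd2, a feedback inhibitor of WNT signalling, went from 390.6 to 995.1 and was 2.13-fold higher, with all 4 of its measured probe sets higher. Notum (1.55-fold), Apcdd1 (1.54-fold) and Lgr5 (1.54-fold) were higher, as was Axin2 (1.36-fold), a standard readout of the pathway, which went from 619.5 to 1005.5. Sox9 was 1.55-fold lower.

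WNT inhibitors and WNT ligands showed no shared difference. Among 14 measured inhibitors 7 lay on each side of 0, with a median of 0.04 (-0.36 against the spikes) at percentile 50.6 and a mean of -0.02. Wif1 was the one inhibitor at least 2-fold lower, and Frzb, with Notum and Apcdd1, was among the higher ones at 0.51. The 23 measured ligands and receptors had a median of 0.07 (-0.34 against the spikes) at percentile 73.3, with Fzd10, a WNT receptor, going from 172.4 to 412.4 and Wnt7a at 0.65.

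**Figure D2:**
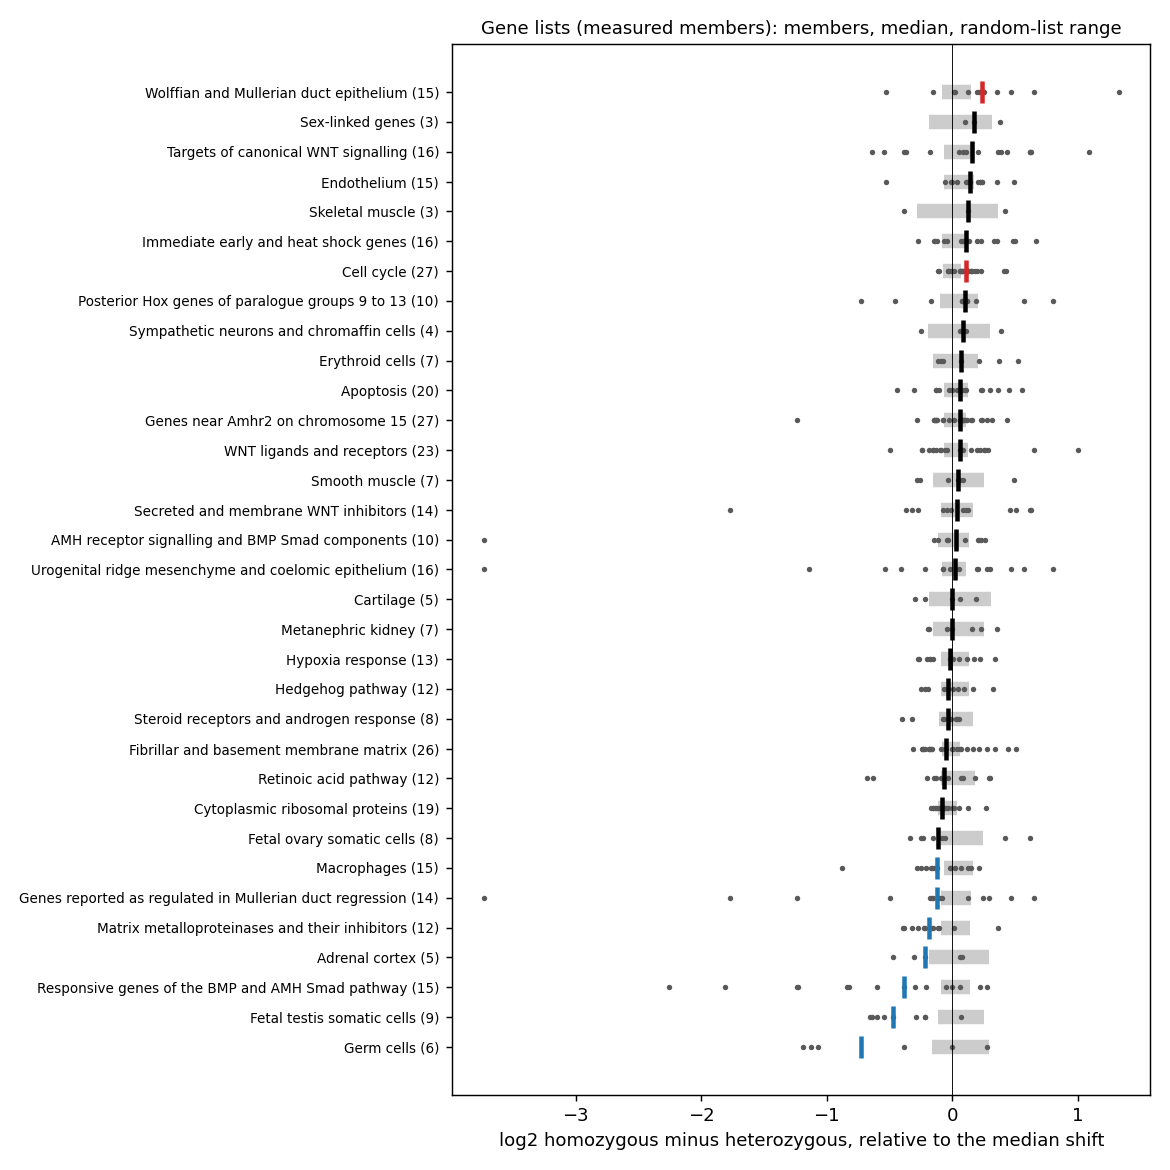
Each line of the plot is a gene list, with the log2 difference, homozygous minus heterozygous, relative to the median shift on the x axis; dots are measured members, the tick is their median, and the grey bar is the central 95% of 10000 random lists matched on mean signal. Medians coloured blue lie below the bar (7 lists) and those coloured red above it (2 lists), among 33 lists; as deposited 4 of the blue medians turn positive, and against the spikes both red medians turn negative.

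Matrix metalloproteinases and their inhibitors also stood on the lower side of random lists. Of 12 measured members 10 were below 0, with a median of -0.19 (0.07 as deposited, where it turns positive) at percentile 0.04 (3.24, inside the central 95%, without a floor), and no member differed 2-fold. Mmp14, a membrane-bound protease, had a log2 difference of -0.39, Timp2, its inhibitor and partner, of -0.38, and Mmp23 of 0.37, while further probe sets of Mmp14 and Timp2 reached 0.01 and 0.06. Structural matrix genes such as collagens and laminins had a median of -0.05 over 26 members, at percentile 14.0, with Eln, the elastin gene, at 0.51 and Col1a1 at -0.31 (0.14 for its other probe set).

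Cell cycle genes were slightly above random lists. Of 27 measured members 21 were above 0, with a median of 0.11 (-0.30 against the spikes, where it turns negative) at percentile 99.8, and no member differed 2-fold. Ccne2 and Aurkb, a cyclin and a mitotic kinase, had log2 differences of 0.43 and 0.41. Apoptosis genes had a median of 0.07 (-0.34 against the spikes) at percentile 78.0 over 20 members. Pmaip1 stood at 0.56, Mcl1, a survival factor, at 0.45 and Bcl2l11 at -0.44, but the 6 measured probe sets of Mcl1 ran from -0.11 to 0.45 and the 5 of Bcl2l11 from -0.59 to 0.23.

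The remaining pathway lists lay inside the central 95% of random lists, although retinoic acid genes fell below it with floors at the 60th (percentile 2.08) and 75th percentile (0.58). Posterior Hox genes had a median of 0.10 (-0.30 against the spikes) at percentile 76.2 over 10 members, with Hoxa11 at 0.80 and Hoxa10 at 0.57, both needed for reproductive tract development, and Hoxc9 at -0.73. Retinoic acid pathway genes had a median of -0.06 (0.20 as deposited) at percentile 6.1 over 12 members, with Aldh1a1, an enzyme that makes retinoic acid, at -0.68 and its receptor gene Rarb at -0.63. Hedgehog genes had a median of -0.03 (0.23 as deposited) at percentile 17.1 over 12 members, and steroid receptor and androgen response genes one of -0.04 (0.22 as deposited) at percentile 16.6 over 8.

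Markers of gonadal cells were lower in the homozygous pool, although gonads had been removed. Of 6 measured germ cell markers 5 were below 0, with a median of -0.72 that was lower than all 10000 random lists. Dazl, an RNA-binding protein of germ cells, went from 277.2 to 145.6, Dppa3 from 301.7 to 165.6 and Dppa5a from 383.1 to 219, all near the floor in the homozygous pool. Of 9 measured fetal testis markers 8 were below 0, with a median of -0.47 that was also lower than all random lists. Defb19 had a log2 difference of -0.66 or lower, Sox9 was 1.55-fold and Cyp17a1, an enzyme of androgen synthesis, 1.52-fold lower. Both medians stayed below 0 as deposited, at -0.47 for germ cells and -0.21 for testis. Amh, an abundant product of fetal Sertoli cells, was under the floor in both pools, at 19 and 5.5. Fetal ovary markers had a median of -0.11 (0.14 as deposited) at percentile 2.59 over 8 members, just inside the central 95%, and fell below that range after loess (2.18), with the floor at the 75th percentile (1.64) and with the median of probe sets (1.76).

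Markers of duct epithelium were higher than random lists in the homozygous pool. Of 15 measured members 13 were above 0, with a median of 0.24 (-0.17 against the spikes, where it turns negative) at percentile 99.9. Sall1 (1.33), Wnt7a and Emx2, a homeobox gene of the urogenital epithelium (0.47), were among the higher members. Gata3, a transcription factor of the Wolffian duct, had a log2 difference of -0.53. Not all members mark duct epithelium alone. Sall1 is the gene described above as needed for kidney development, and Emx2 and Krt19 are also in the following list. Markers of ridge mesenchyme and coelomic epithelium had a median of 0.02 (-0.38 against the spikes) at percentile 56.2 over 16 members. Their mean was -0.21, with Amhr2 and Osr1, a transcription factor of intermediate mesoderm, at least 2-fold lower (Osr1 -1.14). For metanephric kidney, 7 of 19 markers were measured, with a median of -0.00 at percentile 32.5, and Six2, a marker of nephron progenitors, was under the floor in both pools, at 69.2 and 26.3.

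Markers of other cell types had smaller median differences, of which the macrophage and adrenal lists lay outside the central 95% of random lists. Macrophage markers had a median of -0.12 (0.14 as deposited, where it turns positive) at percentile 0.3 over 15 members (3.2 with the floor at the 75th percentile), with Cx3cr1, a chemokine receptor, 1.83-fold lower. Adrenal cortex markers had a median of -0.22 (0.04 as deposited, where it turns positive) at percentile 1.27 over 5 members (21.5 with the floor at the 60th percentile), and Mc2r, the receptor for adrenocorticotropic hormone, stood at -0.30. Hsd3b1 (-0.47) and Cyp11a1 (-0.22, the median itself) are also in the fetal testis list, so these 2 lists are not separate observations. The other members, Scarb1 and Fdx1, were above 0, at 0.06 and 0.08. Endothelial markers had a median of 0.14 (-0.26 against the spikes) at percentile 93.2 over 15 members. Erythroid (0.07), smooth muscle (0.05), skeletal muscle (0.13), sympathetic (0.09) and cartilage (0.00) medians lay inside the central 95%, at percentiles 69.8, 55.8, 67.2, 64.9 and 27.4, and turn negative against the spikes. No hepatocyte marker of 13 and 1 gut marker of 11, Shh, were measured. Across all 33 lists compared, 9 lay outside the central 95% of random lists, where 1.65 would do so if each list behaved like a matched random list. Genes of a pathway or cell type can vary together between 2 single pools, and some lists share genes. The 2 counts therefore do not measure an excess.

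Sex-linked transcripts were similar in the 2 pools. The Y-linked genes Eif2s3y (1199.7 and 1541.9), Kdm5d (526.3 and 710.5) and Uty (548.2 and 855.9) were measured in the heterozygous and homozygous pool, with log2 differences of 0.10, 0.17 and 0.38 that turn negative against the spikes. Probe sets of Kdm5d and of Uty differed in both directions. All 3 probe sets of Xist, the transcript of the inactive X chromosome, were under the floor in both pools, the brightest at 61.5 and 121.4. Usp9y was under the floor in both, and Ddx3y was not analysed here. The 3 measured members of this list had a median of 0.17, at percentile 83.2. The sex of the embryos is not in the labels. Signals of Y-linked genes show that both pools held male ridges, while the share of males was not measured.

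Genes near Amhr2 on chromosome 15 showed no shared difference. Over 27 measured neighbours the median was 0.07 (-0.34 against the spikes), at percentile 84.8, with 16 above and 11 below 0, and Sp7 was the one member that differed 2-fold. Espl1, the separase gene, stood at 0.44 and Eif4b, a translation factor, at -0.28, with its 3 probe sets in both directions.

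Lists of genes that mark tissue handling and RNA quality lay inside the central 95% of random lists, but 2 of them left it under alternatives. Immediate early and heat shock genes had a median of 0.11 (-0.29 against the spikes) at percentile 94.8 over 16 members, with Atf3 at 0.67 or higher (108.6, under the floor, and 221.9), Fos at 0.50 and Ier2 at 0.49. This list stood above the central range with the floor at the 40th percentile (97.8), without a floor (99.3), with the median of probe sets (98.3) and without shared or cross-hybridising probe sets (99.95). Hypoxia genes had a median of -0.02 (0.24 as deposited) at percentile 26.6 over 13 members, and fell below it with the floor at the 75th percentile (0.18) and without shared probe sets (0.7). Cytoplasmic ribosomal protein genes had a median of -0.08 (0.18 as deposited) at percentile 12.4 over 19. The ratio of the 3' to the 5' signal was 1.16 in the heterozygous and 1.21 in the homozygous pool for beta-actin, and 0.81 and 0.85 for Gapdh. The 18 hybridisation spike probe sets had a median of 0.40 relative to the shift of all probe sets, from 0.05 to 0.73, with 4 of the 18 under the floor in the heterozygous pool and taken as deposited.

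The authors' deposited table lists 739 probe sets, 335 higher and 404 lower in the homozygous pool, with no fold under 2. In the authors' deposited table Amhr2 had the lowest fold, -183.565, computed from a signal of 9.2 in the homozygous pool. Msx2 (-6.688), Wif1 (-7.36), Ednrb (-3.633), Sp7 (-3.182) and Spry4 (3.112) are also in the authors' deposited table. Of the 739 probe sets in the authors' deposited table, 503 had both signals under the floor, and 236 were measured here. With the floor and relative to the median shift, 115 of the 739 in the authors' deposited table differed at least 2-fold in the same direction. On the scale that the authors' deposited table uses, 294 measured probe sets reached 2-fold, of which 236 are listed there. Of the 50 genes at least 2-fold apart here, 48 have their probe set in the authors' deposited table, and the other 2 are Zap70 and Hs3st3a1, the latter looked up afterwards.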

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

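The tests of scaling, chromosome 15, dim probe sets, kidney, general epithelium and gonadal tissue for the Smad-responsive genes were chosen after the results were seen, and the test with further germ cell and testis lists before. The 18S ribosomal RNA control probe sets, which belong to no comparison above, were higher in the homozygous pool, with a mean log2 difference of at least 0.93 over 3 probe sets relative to the median shift. Their signals went from 128.6 to 411.3, from 112.5 to 333.1 and from 68.4 to 151.1, so that 2 of the 3 heterozygous signals were under the floor of 116.5. Of 3156 measured probe sets without a single named gene, 11 differed at least 2-fold relative to the median shift, 9 higher and 2 lower in the homozygous pool. This is no larger a share than the 50 of 11432 named genes.

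For the Smad-responsive genes, lower in the homozygous pool, the list stood at percentile 0 of random lists under both quantile normalization and loess. This cannot decide on scaling of the arrays. Both methods move genes largely by their signal, so random lists matched on mean signal move much as the list does. A constant factor moves lists and random lists alike and was no test. What the values show is that the list was lower than genes of like signal under these scalings. Genes carried along with the targeted allele on chromosome 15 are argued against for the list, since 1 of the 15 measured members, Sp7, lies there. Less gonadal tissue in the homozygous pool stays open: Dazl, the lowest marker, was at least 0.33 above the median of the 4 members at least 2-fold lower, a bound because 3 of these 4 were under the floor in the homozygous pool. Whether the gap is within 2 SD of a difference between 2 values (0.66, from the probe set SD of 0.23), the bound for this explanation, is therefore not known. Dazl's own homozygous signal at 1.04 times the floor also limits how low it could read. These 2 reasons were added after the value was seen. Other markers, chosen after their values were seen, went both ways. Aard and Cyp17a1 had homozygous signals of 673.4 and 297.1, further above the floor than that of Dazl. They were 1.46-fold and 1.52-fold lower and Kit was higher (0.28), against 2.34-fold lower for Smad6. Dppa3 and Dppa5a, near the floor, were 2.18-fold and 2.09-fold lower. Loss of the receptor's signal, which the genotypes differ in, may account for the pattern as a hypothesis, and 1 pool per genotype leaves it untested.

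Germ cell and testis markers were lower in the homozygous pool. Bias of dim probe sets is argued against as the whole cause, since after loess, which removes a trend with signal, the medians were -0.74 and -0.49 (-0.72 and -0.47 before). Both lists also stood at percentile 0 of random lists of like signal after loess. The medians were past the probe set SD of 0.27 at dim signals, but that SD describes single genes and not list medians. For less gonadal tissue, further lists of germ cell and testis genes stood at percentiles 52.6 and 87.6, which met the bound written beforehand against this explanation. Among genes that reached 2 floors, the germ cell genes Tex15 (0.24) and Ddx25 (0.06) were above 0, and the testis genes ran from -0.38 (Fgf9) to 0.68 (Cldn11). The bound written beforehand was judged wrong only after the result, because 2 of the 7 further germ cell genes reached 2 floors and the further testis list, with 6 of 9 at 2 floors, held widely expressed genes such as Clu and Mt1 whose baseline could hide a small share. Residual gonad therefore cannot be told apart from lower expression in the ridge, and Amh, under the floor in both pools, decides nothing.

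Duct epithelium markers were above random lists in the homozygous pool, with a median that turns negative against the spikes. The highest member, Sall1 (1.33), is itself needed for kidney development. Metanephric kidney stays open, since the 7 measured of its 19 markers stood at percentile 32.5 with 3 above and 4 below 0; percentiles of 1.32 without a floor and 3 with the floor at the 75th percentile lean against it but rest on dim or only 3 markers, and a bound on the number measured was dropped after it had been met, because a marker under the floor excludes nothing. A larger share of epithelium of every kind stays open as well, since 10 general epithelium genes outside the first list stood at percentile 77.3. Split after its values were seen, the list had 4 Müllerian genes above 0 (Wnt7a, Emx2, Pax8 and Lhx1, median 0.41, 0.01 against the spikes) and the Wolffian genes Gata3 (-0.53) and Wnt9b (-0.15) below, which is no test, since the genes were picked from a list known to be high. A retained Müllerian duct in ridges without the receptor may also account for the pattern, a hypothesis that was not separated from these.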

How the results depend on the processing

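Scaling to the median, to the authors' constants and to the spikes was chosen after the data were seen. No paired analysis was possible because each genotype has 1 array. As deposited, 86 genes were at least 2-fold higher and 10 lower in the homozygous pool. The counts were 24 and 26 with arrays scaled to the 75th percentile, 25 and 25 under quantile normalization, 25 and 25 after loess, 26 and 24 with scaling to the median, 25 and 24 with the authors' constants, and 4 and 96 with scaling to the spikes; the shift between arrays moved them. Of the 86 higher genes 24, 25, 25, 26, 25 and 4 stayed higher under these 6 scalings. The higher count was 148 with the floor at the 40th percentile, and the counts were 51 and 3 at the 60th, 14 and 2 at the 75th, 515 and 175 without a floor, 1140 and 38 at 1.5-fold, and 8 and 5 at 3-fold, since these settings admit more or fewer dim or small differences. Of the authors' 739 probe sets, 83 reached 2-fold in the same direction with the floor, 529 without it, and 721 without it after scaling to the median. Msx2 reversed to 0.22 with the floor at the 75th percentile, where the homozygous floor of 646.2 exceeds its heterozygous signal. A constant factor cannot move a list against random lists, so list percentiles were compared under the other settings only. Of 255 comparisons 232 kept their side, 23 moved and 0 reversed, and 9 to 13 lists lay outside the central 95% of random lists. Lists that moved inside were adrenal with the floor at the 60th percentile (percentile 21.5), adrenal (3.78) and metalloproteinases (3.24) without a floor, and macrophages with the floor at the 75th percentile (3.2). Lists that moved outside were immediate early genes with the floor at the 40th percentile (97.8), without a floor (99.3), with the median of probe sets (98.3) and without shared probe sets (99.95), WNT targets under quantile normalization (97.9), with the floor at the 60th percentile (99.5) and with the median of probe sets (99.9), and fetal ovary after loess (2.18), with the floor at the 75th percentile (1.64) and with the median of probe sets (1.76). So did retinoic acid genes with floors at the 60th (2.08) and 75th percentile (0.58), hypoxia genes with the floor at the 75th (0.18) and without shared probe sets (0.7), kidney (1.32) and erythroid (99.65) without a floor, endothelium with the floor at the 60th (98.1), ridge mesenchyme with the floor at the 75th (99.98) and matrix with the median of probe sets (1.63); the cause was not tested. Of 1576 comparisons of named genes 673 moved by less than the probe set spread, 902 by more and 1, Msx2, reversed, counting as reversed only a gene at least 2-fold apart as deposited that changed sign. Counting every size, 20 named genes changed sign under each of 5 scalings and 55 under scaling to the spikes. The values compared were those as deposited, so scaling by a constant factor moved all named genes by the same amount. The 902 larger moves include this shared shift and are not all changes of single genes. Signals near the floor limit the size of every lower bound. The alternative with detection calls was not run.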

Other observations

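The genes described first were chosen after their values were seen, and the tests on FGF feedback genes and BMP antagonists were written before the list results but after Spry4 and Chrd had been noticed. Among genes at least 2-fold apart that the report does not describe, Acot11, an acyl-CoA thioesterase, went from 693.6 to 365.4, 2.27-fold lower in the homozygous pool, and Me1, the cytosolic malic enzyme, from 592 to 313.7, 2.26-fold lower. Cnr1, the cannabinoid receptor of neurons, went from 376.3 to 941, 2.09-fold higher, and just under the threshold Chrd (chordin, a secreted BMP antagonist) went from 132.5 to 310.2, 1.96-fold higher.

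FGF and ERK feedback genes were higher together, a pattern prompted by Spry4. Without Spry4, 13 of 14 measured members were above 0, with a median of 0.18 at percentile 99.5 of random lists, and Etv5 (0.89, with probe sets in both directions), Dusp6 (0.63), Phlda1 (0.46) and Dusp4 (0.40) were the highest. Of these 14, 4 genes were in lists seen earlier, and without them the median of 10 genes stood at percentile 98.6, while against the spikes the median of all 14 turns negative, at -0.22. Tissue handling can induce some of the same genes, and the immediate early list lay inside the central 95% at percentile 94.8, with Atf3 (0.67 or more), Fos (0.50) and Ier2 (0.49) higher and Zfp36 (-0.14), Junb (-0.13) and Jund (-0.12) lower. Higher FGF or ERK activity or handling may account for the pattern, and these were not separated.

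BMP antagonists lay on both sides of 0. Without Chrd, 5 of 10 measured members were above and 5 below 0, with a median of -0.03 at percentile 15.4 of random lists. This met the bound written beforehand against jointly higher antagonists. The 10 members ran from -0.40 or lower (Nog, the noggin gene, under the floor in the homozygous pool) to 0.40 (Nbl1). This range argues against a joint rise of the size of Chrd (0.97) for these genes. That bound was judged wrong after the result for smaller joint differences, which a median near 0 over such a range leaves undecided.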
